A study of Mus musculus with 56 samples.

How the data were processed

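Footprints and total RNA came from one lysate per sample, per the labels' protocols: lysates were digested with RNase T1 and S7 for footprints, and RNA was depleted of ribosomal RNA and made into directional libraries. The authors deposited raw counts of reads per gene, 1 table per library and 1 table of all 56 libraries, with no normalization. Cutadapt 1.14, STAR 2.5.3 and genome build mm10 are named per the submitters' processing notes; the counting tool and the annotation are not stated. The 56 columns of the joint table were identical to the separate tables. Of 50222 gene identifiers, 49998 were matched to a symbol, 224 were not, and 136 shared a symbol with another. No coordinates were used.

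Samples were grouped by the tissue, assay and age fields of the labels; the field gives 11 months where titles give 10, and 10 was tried as an alternative. Comparisons, tests, gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Genes were filtered with filterByExpr (minimum count 10), scaled by TMM and tested with the quasi-likelihood F test of edgeR 4.0.16 (robust, two-sided, Benjamini-Hochberg at 0.05) in R 4.3.3. All libraries of a tissue and assay were fitted together. Pairwise fits used age groups, the trend used age in months from 3 to 32, and translation efficiency was the interaction of assay and age in 1 model over both kinds of library, with genes passing the filter in both. Errors of log2 differences (SE) were derived from the test, as the absolute log2 difference divided by the square root of F. Levels are CPM with SD. Tests of this kind rest on a model across genes, since an exact permutation test of 3 against 3 cannot give a p under 0.1.

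Genes of 36 lists (pathways, complexes and cell type markers) were counted as called over all genes and as adjusted over the list alone. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), adjusted together over the 8 planned comparisons, and again with an estimated correlation, with fry, with library size only and without the 10 most abundant genes. Fry's directional test asks whether a list's genes move one way and its mixed test whether they change in either direction; neither compares the list with other genes. List tests at 11, 20 and 26 months and at 20 months in kidney were added after seeing the data, as a family of their own.

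Named genes were taken by a rule. For the 1 against 3 months comparison it takes the 5 highest and 5 lowest log2 differences among called genes with a mean of at least 5 CPM and ranges that do not overlap. Predicted gene models and variable segments of antibodies and T cell receptors are counted but not named. The comparisons of 32 with 3 months, where the rule takes 8 each way, had no called gene. For each list it takes up to 4 called members of smallest adjusted p, or up to 2 of the highest level where none was called; some of these genes are not reported here. Tissue and sex markers were named as checks of labels. Genes of the RNA and translation efficiency comparisons were left out, because 14 of 28 RNA libraries failed the tissue check. That check, the matching of RNA to footprint libraries and the list values per library were chosen after seeing the data, except the markers themselves. List means are of log2(CPM plus 1) without TMM scaling, so they are not on the scale of the fits and camera tests.

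Replicate numbers as labelled showed no pairing of libraries. Same-numbered footprint libraries of different ages had a mean correlation of deviations of −0.0472 in liver and 0.0424 in kidney. RNA and footprint libraries of the same label had 0.0501 and 0.0225. Liver and kidney footprint libraries of the same age and number had −0.0483. The labels describe both assays as one lysate per animal, so the fit of translation efficiency with the animal as a block was an alternative, and it called 0 genes. Since 14 of 28 RNA libraries carried the markers of the other tissue, libraries of one label need not share a lysate. The correlations within a label and that fit therefore cannot show whether pairing by animal matters. Age labels of the footprint libraries are in doubt too, so the other correlations cannot exclude a pairing either. The main fit of kidney against liver did not pair the tissues by animal.

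Alternatives were DESeq2 1.42.0, RLE and library-size scaling, no filter, a minimum count of 50, fits of the compared groups alone, a replicate block, each library left out in turn, 32-month libraries summed in pairs because the series states 2 animals at that age, pooled 26 and 32 months, 20 months as the reference, and other codings of age. Protein-coding genes only and RNA libraries with matching markers only (in liver), list tests with a library left out, and list means without the 3-month library of each tissue that stands apart, were added after seeing the data. Tests were checked on simulated counts: of 2-fold and 4-fold differences, 49% and 79.8% were recovered for liver footprints at 32 against 3 months (13372 genes), 29.3% and 85.9% for kidney footprints (14469 genes) and 42.7% and 87.6% for the liver trend (13258 genes), with at most 5 false calls per comparison. Each gene was simulated independently, without the shifts that genes of a real library share. Other splits of the real liver footprints at 32 against 3 months called up to 1071 genes. The simulated false calls therefore do not bound those in these data. Reads carry no molecular identifiers, so counting intervals cover counting error only. Figures were drawn with matplotlib.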

Results

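Ribosome footprints and total RNA were sequenced from liver and kidney of C57BL/6 mice to follow how transcript levels and translation differ along life. Liver was labelled with 6 ages that run from 1 to 32 months (1, 3, 11, 20, 26, 32), with 3 libraries of each kind per age. Kidney was labelled with 3 ages (3 months with 4 libraries of each kind, 20 and 32 months with 3). That makes 56 libraries, 28 of footprints and 28 of RNA. The libraries labelled 11 months carry 10m in their titles. The series describes 2 animals at 32 months, while 3 libraries of each kind carry that label in each tissue. It describes 3 animals at the other ages, while 4 kidney libraries of each kind are labelled 3 months, so n counts libraries and may exceed the number of animals. Total counts per library ran from 7985755 to 26921222 in liver footprints, from 10388818 to 30517983 in kidney footprints, from 2551502 to 16380508 in liver RNA and from 3342997 to 16562937 in kidney RNA. The 3 RNA libraries labelled liver at 3 months had from 2551502 to 3606794.

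Tissue markers matched the label in 28 of the 28 footprint libraries and in 14 of the 28 RNA libraries. Alb, the main plasma protein made by hepatocytes, lay between 30523 and 123575 CPM (counts scaled to the library total) in the 18 liver footprint libraries and between 9.23 and 126 CPM in the 10 kidney ones. Kap, an androgen-regulated gene of the proximal tubule, lay between 988 and 23354 CPM in kidney footprints and reached at most 13.3 CPM in liver footprints. Among RNA libraries, 7 of the 18 labelled liver showed a kidney profile and 7 of the 10 labelled kidney showed a liver profile. The RNA libraries with a kidney profile had at most 462 CPM of Alb, and those with a liver profile had at most 19.6 CPM of Kap. Xist stayed at or below 0.248 CPM in every library and Ddx3y, on the Y chromosome, at or above 12.7 CPM, so all 56 libraries had the marker pattern of males. The labels do not give the sex.

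**Figure D1:**
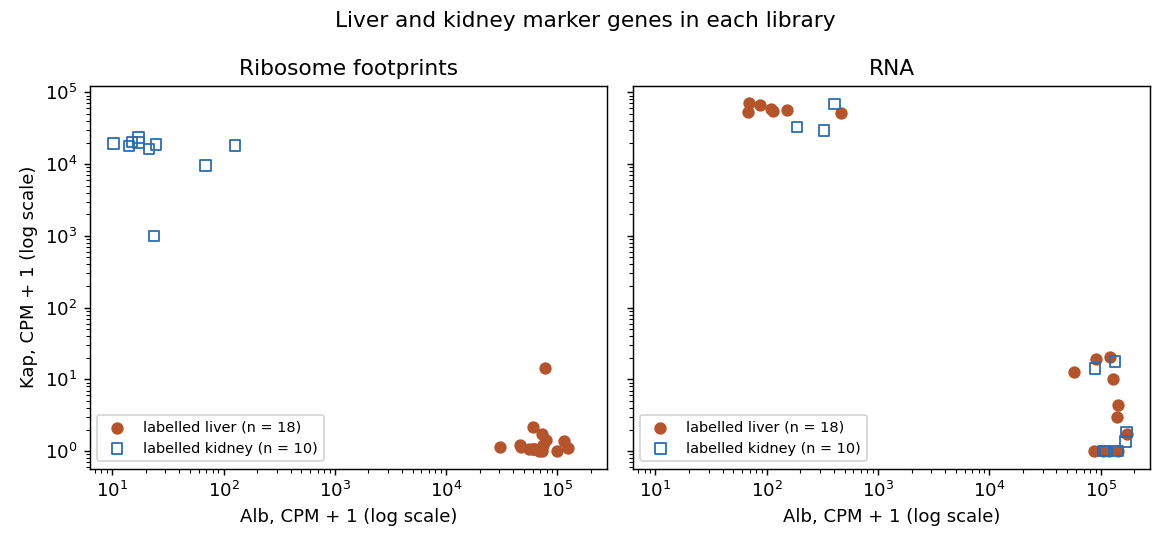
Level of Kap against level of Alb (CPM plus 1, both axes logarithmic), 1 point per library; filled circles carry a liver label (n = 18 per panel) and open squares a kidney label (n = 10). In footprints the labels separate the points, while 7 liver-labelled and 7 kidney-labelled RNA libraries lie with the other tissue.

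RNA and footprint libraries were also compared gene by gene, as deviations from the mean of their profile. Only the 400 genes whose variances in both assays had the highest product were used, so the correlations are not genome-wide. None (0 of 28) of the RNA libraries was closest to the footprint library of its own label, and 27 of 28 formed a mutual closest pair with a footprint library of another label. The correlation across genes with the closest footprint library had a median of 0.9 (range 0.632 to 0.976). With the footprint library of the own label it had a median of 0.0111 over the 14 libraries where both had 1 profile. The highest of these was 0.559, for RNA library 2 labelled kidney at 3 months, the only one without a mutual pair. Its own label came second to another library at 0.632, so a correct label is not excluded there. That other library formed its mutual pair with RNA library 3 labelled kidney at 20 months (0.915). The 27 pairs used 27 distinct footprint libraries, so the only one left unpaired was that of its own label. This footprint library stands apart from the other kidney footprints, which limits what its lower correlation can show. Genes are not independent replicates, so these correlations describe libraries. Results that use RNA are therefore given only as counts and as medians over all genes, for the libraries as labelled.

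Age markers in the liver footprints did not follow the age labels either. H19, an imprinted transcript high in fetal and newborn liver, was at 14.7 ± 6.57 CPM (SD, n = 3) in the libraries labelled 11 months and at 0.203 ± 0.207 CPM (SD, n = 3) in those labelled 1 month. Immunoglobulin transcripts, made by B and plasma cells, were lowest in libraries labelled 1 and 11 months: Ighm was at 6.12 ± 2.0 and 5.09 ± 1.34 CPM (SD, n = 3 each), against 321.8 ± 422.6 CPM (SD, n = 3) in those labelled 3 months, where libraries 1, 2 and 3 had 805.5, 135.7 and 24.1 CPM. Every direction with age given for footprints holds for the libraries as labelled, and these markers go against the labels.

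**Figure D2:**
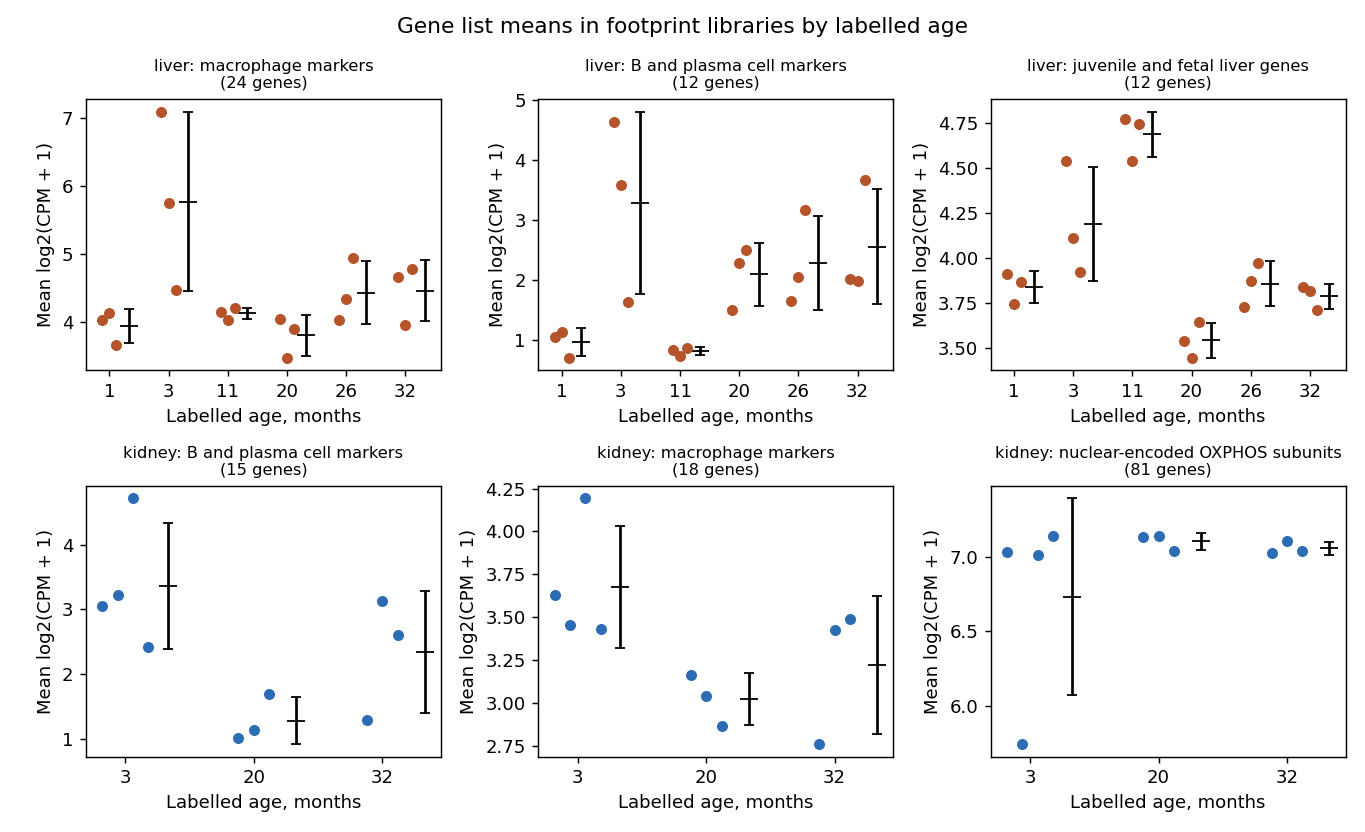
Mean log2(CPM plus 1) of gene lists in 6 panels by labelled age in months, 1 point per footprint library, with the mean and SD of each age beside the points (n = 3, kidney at 3 months n = 4). The juvenile list is highest in the libraries labelled 11 months (4.69 ± 0.13), and kidney library 2 labelled 3 months lies apart at 5.74 for oxidative phosphorylation.

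The comparison of 32 with 3 months asks how translated transcripts differ between old and young adult liver, by the labels. Lists of macrophage, neutrophil, matrix and cell cycle genes had negative medians in the libraries labelled 32 months, but no single gene passed the test. Lyz2, a lysozyme of macrophages and neutrophils, was at 128.6 ± 37.7 CPM (SD, n = 3) in the libraries labelled 32 months and at 404.5 ± 278.2 CPM (SD, n = 3) in those labelled 3 months. Of 24 macrophage markers, 0 were called by edgeR over all genes and 21 were lower when adjusted over the list alone, with a median log2 difference of −1.45. Clec4f, a receptor of Kupffer cells, had a log2 difference of −1.80 ± 0.53 (SE, adjusted p = 0.0879, edgeR). Of 28 cell cycle genes, 22 were lower when adjusted over the list alone, with a median of −1.53. Pcna, the sliding clamp of DNA polymerase, had a log2 difference of −0.49 ± 0.13 (SE). Of 28 matrix and fibroblast genes, 13 were lower when adjusted over the list alone (median −0.71). Among 6 neutrophil markers this held for 5 (median −2.82). Female-biased liver genes were lower in 8 of 14 when adjusted over the list alone, Slc22a26 with a log2 difference of −2.67 ± 0.70 (SE). Male-biased genes had a median of 0.94 over 19 members, and 1 was higher by that count.

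In the set test with a preset correlation (camera), 16 of 33 lists were called in liver, 5 higher and 11 lower. The higher ones were oxidative phosphorylation (80 genes, median log2 0.32, adjusted p = 9.49e-14), mitochondrial ribosomal proteins (77 genes, median 0.22, adjusted p = 4.15e-07), male-biased genes, fatty acid oxidation (22 genes, median 0.48) and drug-metabolizing enzymes (27 genes, median 0.33). Among the lower ones were macrophage markers (adjusted p = 3.58e-10), cell cycle genes (adjusted p = 1.17e-09) and matrix genes (adjusted p = 7.01e-08). With an estimated correlation every list lost its call, with an adjusted p of 0.702 or more. Atp5b, the catalytic subunit of ATP synthase, had a log2 difference of 0.31 ± 0.21 (SE). edgeR tested 13608 genes and called 0, with 2596 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0667, and DESeq2 called 825 (201 higher, 624 lower). Leaving out library 3 of the 3-month group gave 2085 genes (596 higher, 1489 lower), leaving out library 1 of the 32-month group gave 39 (31 higher, 8 lower), and leaving out library 2 of the 3-month group gave 2. Library 1 labelled 3 months stood apart from the other liver footprints, with a median correlation of 0.918 across genes. Without it the difference in list means went from −1.36 to −0.15 log2 for neutrophil markers (camera adjusted p = 0.716), from −1.31 to −0.64 for macrophage markers, from −0.95 to −0.40 for cell cycle genes, from −0.74 to −0.40 for matrix genes and from 0.20 to 0.08 for oxidative phosphorylation. It went from 0.26 to 0.02 for drug-metabolizing enzymes (camera adjusted p = 0.791), from 0.06 to 0.03 for mitochondrial ribosomal proteins, from 1.94 to 1.08 for male-biased genes and from 0.24 to 0.15 for fatty acid oxidation. These list means are of CPM without TMM scaling, unlike the medians and camera tests. With all libraries, mitochondrial ribosomal proteins differed by 0.06 in list mean but by 0.22 in TMM-scaled median. The size of that difference thus depends on the scaling.

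In kidney footprints the question of old against young adults, by the labels, gave no called gene either. Antibody transcripts were lower on average in the libraries labelled 32 months, Ighm at 143.2 ± 136.3 CPM (SD, n = 3) against 569.9 ± 635.1 CPM (SD, n = 4), a difference within the spread between replicates. Lyz2 was at 33.3 ± 10.8 against 58.8 ± 20.1 CPM (log2 difference −0.81 ± 0.27, SE, adjusted p = 0.785, edgeR). C3, the central complement component, had a log2 difference of −1.50 ± 0.37 (SE) and was not called. Median log2 differences were −1.05 over 17 B and plasma cell markers, −0.63 over 20 macrophage markers and −0.49 over 28 interferon response genes. They were 0.22 over 82 oxidative phosphorylation subunits, 0.28 over 37 proteasome subunits and 0.20 over 22 proximal tubule markers. None of these 6 lists had a called member, over all genes or over the list alone. Umod, made in the thick ascending limb, was at 5183 ± 776 against 4786 ± 2025 CPM (SD), with 2181 CPM in library 2 labelled 3 months and 4647 to 7087 CPM in the other 3 of that age.

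Camera called 16 of 34 lists in kidney, 4 higher and 12 lower, and none (0) with an estimated correlation (adjusted p of 0.702 or more). Library 2 labelled 3 months had a median correlation of 0.906 with the other kidney footprints, which had at least 0.977, and only 988 CPM of Kap. Without it, oxidative phosphorylation and proximal tubule markers changed direction in camera and lost their calls (adjusted p = 0.556 and 0.855), and proteasome subunits and mitochondrial ribosomal proteins lost theirs (adjusted p = 0.616 and 0.801). The difference in the proteasome list mean went from 0.31 to 0.02 log2 and that of oxidative phosphorylation from 0.33 to −0.00492, so the higher values of these 4 lists rest on that library. edgeR then called 1 gene. With all libraries edgeR tested 14621 genes and called 0, with 632 at an unadjusted p under 0.05, against 731 given by chance, and DESeq2 called 2.

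Kidney libraries labelled 20 months were also compared with those labelled 3 months, and no gene was called. Ighm was at 22.1 ± 13.6 CPM (SD, n = 3) against 569.9 ± 635.1 CPM (SD, n = 4), with ranges that did not overlap (8.56 to 35.8 against 88.2 to 1501). Igkc, the constant part of the kappa light chain, had a log2 difference of −5.25 ± 1.25 (SE, adjusted p = 0.184, edgeR). Of 17 B and plasma cell markers, 9 were lower when adjusted over the list alone (median −2.18), as were 10 of 20 macrophage markers (median −0.72) and 8 of 18 circadian clock genes (median −0.55), with 1 other clock gene higher. The mean of 6 pancreas and fat markers was 5.10 ± 0.53 against 3.55 ± 1.24 log2 (SD), a difference of 1.54, or 1.84 without library 2 labelled 3 months (camera adjusted p = 0.00645, or 0.487 with an estimated correlation). Over all genes edgeR called 0 of 14621, with 1981 at an unadjusted p under 0.05, and DESeq2 called 385 (99 higher, 286 lower). Leaving out library 2 of the 3-month group gave 255 calls, 91 higher and 164 lower. Without it the difference in list means went from 0.37 to 0.04 log2 for oxidative phosphorylation, from 0.37 to 0.07 for proteasome subunits, from 0.25 to 0.05 for mitochondrial ribosomal proteins and from 0.25 to −0.05 for lysosomal proteins. Camera called 20 of 34 lists (8 higher, 12 lower), and 0 with an estimated correlation (adjusted p = 0.487 for B and plasma cell markers, 0.357 for the clock).

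Liver footprints labelled 1 month were compared with those labelled 3 months, weanlings against young adults by the labels. Immune transcripts were lower in the 1-month libraries: all 24 of 24 macrophage markers were called lower, over all genes and over the list alone (median log2 −2.01). Trem2, a lipid receptor of macrophages, had a log2 difference of −5.48 ± 0.76 (SE, adjusted p = 0.00229, edgeR), and Gpnmb, a glycoprotein of activated macrophages, one of −5.73 ± 0.83. Lyz2 was at 65.4 ± 12.7 against 404.5 ± 278.2 CPM (SD, n = 3 each). Neutrophil markers were called lower in 6 of 6 (6 over the list alone), among them S100a8 (−4.26 ± 0.95). Of 18 B and plasma cell markers 10 were called lower and 1 higher (16 and 1 over the list alone), Igha at −4.99 ± 0.89 and Ighm at −5.43 ± 1.09. Lysosomal proteins were called lower in 14 of 25 (17 over the list alone, median −0.58). Interferon response genes were called lower in 7 of 30 (9 over the list alone, Oasl2 at −2.19 ± 0.57) and cell cycle genes in 8 of 28 (14 over the list alone; Mki67, a marker of proliferation, at −3.13 ± 0.72). Erythroid markers were called lower in 6 of 8 (7 over the list alone, Hbb-bt at −1.34 ± 0.27), and senescence-associated genes in 5 of 16 (11 over the list alone), led by the cell cycle inhibitor Cdkn1a at −3.63 ± 0.81.

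Genes of sex-biased liver metabolism differed too. Female-biased genes were called lower in 7 of 14 (10 over the list alone), with Cyp2b9, a cytochrome P450, at 0.0933 ± 0.108 against 18.2 ± 17.0 CPM (SD, n = 3 each). Male-biased genes were called higher in 3 of 19 (12 over the list alone): Elovl3, a fatty acid elongase, was at 185.9 ± 36.6 against 18.8 ± 17.1 CPM. Mitochondrial ribosomal proteins were called higher in 11 of 77 (26 over the list alone, Mrps22 at 0.72 ± 0.17), and 3 of 26 ER chaperone genes were called higher (5 over the list alone, Pdia6 at 0.83 ± 0.21). Among juvenile and fetal liver genes, 1 of 12 was called higher and 3 lower (1 and 4 over the list alone), with H19 at −2.58 ± 0.65. Of 883 genes eligible by the rule, the 5 with the highest differences were Mup17 (6.93 ± 1.02), Mup18 (5.22 ± 0.90), Ugt2b38 (3.72 ± 0.61), Elovl3 (3.30 ± 0.64) and Mup14 (3.23 ± 0.71). Mup genes encode major urinary proteins and are near-identical copies, so the split of reads between them is uncertain. The lowest were Cyp2b9 (−7.28 ± 1.20), Ighg2b (−6.46 ± 1.52), Slc22a26 (−6.00 ± 0.92), Igkc (−5.74 ± 1.16) and Ighg2c, which had 1 count in the 1-month libraries and 861 in the 3-month ones. The Ighg2c ratio was 0.00175 (95% exact interval 4.42e-05 to 0.00977, counting error only).

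edgeR called 1674 of 13608 genes between these groups, 463 higher and 1211 lower. Scaled by library size only, the calls split into 259 higher and 1243 lower (17.2% higher against 27.7%). No gene was called when only the 6 compared libraries were fitted (2590 at an unadjusted p under 0.05), and left-out libraries moved the count between 224 (without library 3 labelled 1 month) and 3240 (without library 3 labelled 3 months). Without libraries 1 and 2 labelled 1 month it was 941 and 571, and without library 1 labelled 3 months 331. That last library carried much of several list differences. For neutrophil markers the 3-month list means ran from 0.504 to 4.71 log2, against 0.364 to 0.659 at 1 month, and without library 1 the difference went from −1.78 to −0.57. For cell cycle genes they ran from 1.60 to 3.79 against 1.65 to 2.17, and the difference went from −0.86 to −0.31. It went from −0.82 to −0.24 for interferon response genes (camera adjusted p = 0.213 without library 1), from −1.82 to −1.16 for macrophage markers, from −0.70 to −0.46 for lysosomal proteins and from 2.43 to 1.58 for male-biased genes. Camera called 22 of 33 lists (6 higher, 16 lower), and 0 with an estimated correlation (adjusted p of 0.702 or more).

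The libraries labelled 11 months differed from those labelled 3 months in genes of sex-biased and early-life liver expression. Female-biased genes were called higher in 8 of 14 (10 over the list alone, median 2.58), among them Hao2, a peroxisomal oxidase, at 6.63 ± 0.49 (SE, adjusted p = 1.34e-05, edgeR). Juvenile and fetal genes were called higher in 4 of 12 and lower in 1 (6 and 1 over the list alone), H19 at 3.61 ± 0.49 and Gpc3 at 2.38 ± 0.46. Matrix genes went both ways, 7 of 28 called higher and 4 lower (9 and 4 over the list alone): Sparc (1.80 ± 0.19) and Col3a1 (2.02 ± 0.35) higher, Timp2 (−1.21 ± 0.25) lower. Male-biased genes were called lower in 5 of 19 (5 over the list alone), among them Mup20 (−1.83 ± 0.47) and Cyp7b1 (−2.66 ± 0.48). Immune lists were lower: 19 of 24 macrophage markers (23 over the list alone), 13 of 23 antigen presentation genes (16 over the list alone, Cd74 at −2.58 ± 0.52), 11 of 18 B and plasma cell markers with 1 higher (14 and 1), and 6 of 6 neutrophil markers (6). Fatty acid oxidation genes were called higher in 8 of 22 and lower in 1 (13 and 1 over the list alone, Fabp1 at 2.30 ± 0.45, Cd36 at −1.37 ± 0.32), globin and other erythroid genes higher in 4 of 8 (4 over the list alone, Hbb-bs at 1.09 ± 0.27), and mitochondrial ribosomal proteins higher in 23 of 77 (32 over the list alone). edgeR called 1881 of 13608 genes, 638 higher and 1243 lower, or 324 and 1827 with library size only. Left-out libraries gave between 767 (library 2 labelled 11 months) and 3131 (library 3 labelled 3 months); without libraries 1 and 3 labelled 11 months it was 1150 and 990, and without library 1 labelled 3 months 883. Without that library the difference in list means went from −1.64 to −0.98 log2 for macrophage markers, from −1.82 to −0.60 for neutrophil markers, from 0.17 to 0.51 for matrix genes and from −0.21 to −1.07 for male-biased genes. Camera called 22 of 33 lists, and 0 with an estimated correlation (smallest adjusted p = 0.357, for juvenile and fetal genes).

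Libraries labelled 20 months had more transcripts of mitochondrial proteins and fewer of immune, matrix and dividing cells than those labelled 3 months. Oxidative phosphorylation subunits were called higher in 44 of 80 (67 over the list alone, median 0.58), with Ndufb8 at 0.76 ± 0.17 (SE, adjusted p = 0.00925, edgeR), and mitochondrial ribosomal proteins in 36 of 77 (56 over the list alone, median 0.48). Fatty acid oxidation genes were called higher in 10 of 22 (11 over the list alone), fatty acid synthesis genes in 4 of 14 (4, Me1 at 1.69 ± 0.41, Elovl5 at 1.40 ± 0.33) and proteasome subunits in 10 of 38 (22, Psmd4 at 0.57 ± 0.15). On CPM without TMM scaling the proteasome list mean differed by only 0.03 log2. That of mitochondrial ribosomal proteins was 4.47 ± 0.05 against 4.25 ± 0.05 log2 (SD), a smaller step than their median of 0.48. The size of these differences thus depends on the scaling. Macrophage markers were called lower in 23 of 24 (24 over the list alone, median −2.10, Trem2 at −5.78 ± 0.79), matrix genes in 19 of 28 (21, Col5a2 at −2.63 ± 0.43), cell cycle genes in 14 of 28 (21, Mki67 at −4.46 ± 0.80) and interferon response genes in 14 of 30 (20, Oas2 at −3.23 ± 0.70). Senescence-associated genes were called lower in 8 of 16 (12 over the list alone), led by the chemokine Cxcl1 (−2.86 ± 0.52). edgeR called 2558 of 13608 genes, 1014 higher and 1544 lower, or 272 and 2517 with library size only. Left-out libraries gave between 370 (library 2 labelled 20 months) and 4132 (library 3 labelled 3 months); it was 1172 and 1634 without libraries 1 and 3 labelled 20 months, and 475 without library 1 labelled 3 months. Without that library the difference in list means went from −1.96 to −1.30 log2 for macrophage markers, from −1.14 to −0.59 for cell cycle genes, from −1.21 to −0.62 for interferon response genes and from 0.35 to 0.23 for oxidative phosphorylation. Camera called 25 of 33 lists (10 higher, 15 lower), and 0 with an estimated correlation (smallest adjusted p = 0.487).

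At 26 against 3 months a single gene was called: Dio1, the deiodinase that activates thyroid hormone, at 172.6 ± 14.98 against 40.3 ± 9.07 CPM (SD, n = 3 each; log2 2.24 ± 0.25, adjusted p = 0.00119, edgeR). It lies outside the rule for named genes and was chosen after its values were seen. Adjusted over the list alone, 21 of 24 macrophage markers (median −1.52), 21 of 28 cell cycle genes (median −1.67) and 6 of 6 neutrophil markers were lower. Of 13608 genes, 2116 had an unadjusted p under 0.05, and DESeq2 called 500. Without library 3 labelled 3 months the count was 1735, and without library 2 labelled 26 months it was 5. Without library 1 labelled 3 months the difference in list means went from −1.34 to −0.67 log2 for macrophage markers, from −0.89 to −0.33 for cell cycle genes and from −1.53 to −0.32 for neutrophil markers. Camera called 22 of 33 lists, and 0 with an estimated correlation.

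Along labelled ages from 3 to 32 months no liver footprint showed a called trend. The slope of Pcna was −0.0164 ± 0.00424 and that of the neutrophil gene S100a9 −0.106 ± 0.0388 log2 per month (SE, adjusted p = 0.114 and 0.199, edgeR). Cyp2a4, a female-biased cytochrome P450, had a slope of −0.328 ± 0.0854 log2 per month, but its mean level was highest at 11 months, at 300.1 ± 216.7 CPM against 13.5 ± 15.5 CPM at 3 months (SD, n = 3 each). edgeR tested 13562 genes over 15 libraries and called 0, with 2047 at an unadjusted p under 0.05, and DESeq2 called 304. With log2 of age 472 genes were called (32 higher, 440 lower), and without library 3 labelled 3 months 506.

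Whether the 32 against 3 months difference itself differed between kidney and liver footprints was tested as an interaction. edgeR tested 15496 genes and called 0, with 1330 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0961, and DESeq2 called 9. Without library 3 labelled 3 months in liver 200 genes were called, and without library 1 labelled 32 months in liver 2. In data simulated from these libraries this test recovered 6.19% of 2-fold and 46.5% of 4-fold differences, so most 2-fold differences between the tissues would be missed.

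The RNA libraries were tested as labelled, although 14 of 28 carried the markers of the other tissue. Among those labelled kidney, these were 3 of 3 at 32 months, 2 of 3 at 20 months and 2 of 4 at 3 months. Kidney comparisons that use RNA thus contrast tissue profiles as well as labelled ages. In edgeR, RNA gave 0 called genes at 32 against 3 months in liver (92 of 13261 at an unadjusted p under 0.05, 0 by DESeq2) and in kidney (650 of 12004, 110 by DESeq2). It gave 0 at 1 against 3 months in liver (125, 1 by DESeq2), and at 11, 20 and 26 against 3 months (277, 260 and 168; 0, 117 and 1 by DESeq2). It gave 0 for the liver age trend (74 of 12892, 0 by DESeq2), for kidney at 20 against 3 months (72 of 12004, 0 by DESeq2) and for the kidney against liver difference (268 of 12587, 12 by DESeq2). Translation efficiency, the change in footprints relative to RNA, gave 0 called genes by edgeR at 32 against 3 months in liver (484 of 12043, 1 by DESeq2), in kidney (1330 of 11568, 178 by DESeq2) and along age in liver (316 of 11836, 0 by DESeq2). In simulated data with the spread of the liver RNA libraries, 0% of 2-fold and 11.1% of 4-fold differences were recovered, so these counts of 0 do not show that liver RNA was alike across ages. For liver translation efficiency at 32 against 3 months 7.29% and 55.7% were recovered, so most 2-fold differences would be missed there too. Camera called 8, 18 and 11 lists in the 3 RNA comparisons tested and 13 and 18 in translation efficiency, and 0 in any of them with an estimated correlation.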

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

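The tests of explanations in this part, and the counts of other splits of the samples, were written down after the results they concern had been seen.

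In the kidney footprints labelled 3 months (4 libraries), library 2 lay far from the other 3 in 8 list means. Its gap to the nearest library, as a share of the group's range, was 0.979 for lysosomal proteins (6.83 against 8.01 to 8.04, mean log2), 0.968 for proteasome subunits, 0.913 for oxidative phosphorylation (5.74 against 7.02 to 7.14), 0.903 for mitochondrial ribosomal proteins, 0.874 for proximal tubule markers (9.25 against 10.4 to 10.6), 0.871 for cytosolic ribosomal proteins, 0.842 for mitochondrially encoded proteins and 0.831 for ER chaperones. In the kidney RNA labelled 3 months, library 4 had a total count of 9339340 against 3342997 to 4038001 (0.884). Of 44 quantities examined 9 passed this bound. Chance gives about 1 in 20 of independent quantities, but 8 of the 9 come from a single library, so the number is no measure against chance.

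Library 2 had 67058 CPM of Rpph1 and 36818 CPM of Rn7sk, both structural RNAs, against at most 9737 and 6627 in the other 9 kidney footprints, and 0.344% mitochondrial counts against at least 2.02%. Structural RNA taking up counts, as the only cause, predicts a deviation that goes away among protein-coding genes. Over these its median correlation with the others was still 0.898, below the lowest of the other 9 (0.978), which argues against it. A lower share of proximal tubule cells would raise markers of other segments, but those were at −0.581 log2 relative to the mean of the other 9 (SD 0.102), while endothelial markers were 0.26 above it. The labels describe a shared lysate for footprints and RNA. Library 2 had 988 CPM of Kap, 3470 of Slc34a1 and 2181 of Umod. All 10 RNA libraries with a kidney profile had at least 29178, 7422 and 5027 CPM of these. That argues against a loss of these transcripts already in the tissue, if its RNA library is among the 10. Damage during footprint preparation, or to other transcripts, stays open and was not tested, and neither was any biological explanation.

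The tissue labels of 14 RNA libraries go against their markers. Mixing in of the other organ is argued against by the highest level of the marker of the labelled tissue, 0.808% of the lowest level in RNA libraries of that profile. A candidate explanation is that names were permuted among the RNA libraries: 27 of 28 formed mutual closest pairs with a footprint library of another label. Which name belongs to which library was not assigned, and no biological explanation was tested.

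Age-linked lists did not follow the age labels of the footprint libraries. Age as labelled would put juvenile and fetal genes highest at 1 month; the 11-month libraries were 0.847 log2 higher than the 1-month ones, each above each. A candidate explanation is that values in order of age were stored under names sorted as text. For kidney, that order, taken as groups of 4, 3 and 3 libraries, ranked 4 of 4200 possible arrangements by separation of the groups (0.0952%), while the labels ranked 386 (9.19%). With genes scaled to equal variance the ranks were 14 and 658. The separation depends only on which libraries share a group, not on which group has which age. It therefore cannot show that the values are in order of age. The order was found and tested on the same data. In liver it would run 11, 1, 20, 26, 32 and 3 months by label. Libraries labelled 3 months, the reference of each liver comparison, would then be the oldest. Means of B and plasma cell markers in that order were 0.81, 0.96, 2.10, 2.29, 2.55 and 3.28 log2 (1.63 to 4.64 in the last). The juvenile list was highest under the first label (4.69) but next highest under the last (4.19). These lists were picked after seeing the values, and the order within liver was not tested. No biological explanation other than age was tested.

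Liver and kidney moved in opposite ways in every 32-month library, against the 3-month mean, for 3 of 32 lists: cytosolic chaperones (kidney minus liver 0.373 log2), lysosomal proteins (0.656) and proximal tubule markers (0.633). All 3 rest on kidney library 2 labelled 3 months: without it the kidney differences were −0.0162, −0.0735 and 0.0139 log2, and 0 of the 3 lists stayed higher in every 32-month kidney library. These list differences were not tested.

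Other splits of the same libraries were counted for each comparison. With 3 against 3 libraries the 10 splits are too few for a share under 0.05: for liver footprints the real count and the highest other were 1674 and 643 at 1 against 3 months (1 split as large), 1881 and 1 at 11 (1), 2558 and 367 at 20 (1), 1 and 867 at 26 (3), and 0 and 1071 at 32 (10). The last 2 point to a structure of the samples other than the labels. For liver RNA at 1, 11, 20, 26 and 32 months, and for liver translation efficiency at 32, the real and the highest other count were 0 (10 of 10 splits each). In the rest the real count was 0, so every split gave as many by construction and the splits say nothing about chance: 35 of 35 for kidney footprints at 32 and 20 against 3 months (highest other 0), kidney RNA at 32 (0) and 20 (6720) and kidney translation efficiency (0), and 100 of 100 drawn for the footprint trend (42), the RNA trend (3454), the translation efficiency trend (2103), the kidney against liver footprints (484) and the same in RNA (2966). The high counts in RNA point to a structure of the samples, which include both tissue profiles.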

How the results depend on the processing

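Protein-coding genes only, RNA libraries with matching markers only, list tests with a library left out, and list means without the 3-month library of each tissue that stands apart were chosen after seeing the data. RLE scaling and protein-coding genes moved no footprint count by over 1.5 times, nor did a minimum count of 50 where it was run. At 11, 20 and 26 months in liver and 20 in kidney, some settings were not run. These were no filter, the minimum count of 50, the compared libraries alone and the replicate block. The 1881 and 2558 calls in liver footprints at 11 and 20 months were thus not put to the compared libraries alone. Replicate numbers only share a number across ages; the replicate block left 1252 calls for liver footprints at 1 against 3 months and called 0 in every other comparison where it was run, as without it. DESeq2 called 825 genes for liver footprints at 32 against 3 months, 2 in kidney, 304 in the trend, 9 in the kidney against liver comparison, 500 at 26 and 385 in kidney at 20 months; in RNA 110 (kidney, 32), 1 (liver, 1), 117 (liver, 20), 1 (liver, 26) and 12 (kidney against liver); in translation efficiency 1 (liver) and 178 (kidney). No filter gave 113 (liver footprints, 32), 1 (kidney against liver footprints), 1 (kidney RNA, 32) and 1 (kidney translation efficiency). Pooled 26 and 32 months gave 805, log2 of age 472, and the compared libraries alone 0 for liver footprints at 1 month and 1 for kidney RNA at 32, where summing libraries 1 and 3 also gave 1. Library size only gave 2 (liver footprints, 26), 1 (kidney RNA, 32) and 1 (kidney translation efficiency); a minimum count of 50 gave 1 there. The cause was not tested, except that pooling adds libraries and the compared libraries alone have fewer.

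Library size only moved the median of all genes in liver footprints to −0.15 at 32, −0.23 at 11, −0.30 at 20 and −0.13 at 26 months, and to 0.17 between kidney and liver. In RNA it was −0.65 (kidney, 32), 0.15 (liver, 1), −0.52 (liver, 20), 0.42 (liver, 26), −0.17 (kidney, 20) and −0.68 (kidney against liver), and in translation efficiency −0.18 (liver) and 0.62 (kidney). The share of higher calls fell to 15.1% from 33.9% at 11 months and to 9.75% from 39.6% at 20.

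With a library left out, liver footprint counts ran from 0 to 2085 (32), 224 to 3240 (1), 767 to 3131 (11), 370 to 4132 (20), 1 to 1735 (26), 0 to 506 (trend) and 0 to 200 (kidney against liver), and kidney ones from 0 to 1 (32) and 0 to 255 (20). Named genes that were called kept direction under the planned and added settings, 1266 of 1435 values still called and 169 not; with a library left out 1021 of 1644 were called and 623 not.

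With an estimated correlation 0 lists were called in any comparison, and by directional fry 0 in the planned ones and 8, 12, 1 and 1 at 11, 20 and 26 months in liver and 20 months in kidney. Mixed fry called 1 (liver footprints, 32), 0 (kidney footprints), 14 (liver footprints, 1) and 0 in RNA and translation efficiency, and 15, 16, 5 and 7 at 11, 20 and 26 months in liver and 20 months in kidney. 7 lists, called or not, changed direction with a library left out. For the interferon response list of liver footprints at 32 against 3 months the adjusted p was 0.00624 without library 3 labelled 3 months, and 0.000477 to 0.576 over those that kept direction. For the cytosolic ribosomal proteins list at 1 against 3 months it was 0.766 without library 3 labelled 1 month, and 1.27e-05 at the lowest. In kidney footprints 5 lists turned at 32 against 3 months without library 2 labelled 3 months. The values there were 0.556 for the nuclear-encoded oxidative phosphorylation subunits list (lowest 1.81e-09), 0.000646 for the mitochondrially encoded proteins list (highest 0.734), 0.00837 for the ER chaperones and translocon list (highest 0.977), 0.0232 for the lysosomal proteins list (0.0076 to 0.264) and 0.855 for the proximal tubule markers list (lowest 0.000583). The cause was not tested. The RNA labelled liver at 3 months had the lowest range of total counts of any group (2551502 to 3606794).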

Other observations

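These values were chosen for description after the data were seen, and none was tested.

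Fat-derived transcripts varied between kidney pieces of one label: Cfd, the adipocyte protein adipsin, ran from 4.1 to 167.1 CPM in the 4 libraries labelled 3 months, from 122.8 to 389.5 in those labelled 20 months and from 14.95 to 77.3 in those labelled 32 months. In liver, library 1 labelled 3 months had 50.6 CPM of Mki67, 37.3 of S100a9 and 805.5 of Ighm, against 2.2, 0.297 and 24.1 CPM in library 3 of the same label. Serpina1e, a male-biased protease inhibitor, was at 1004 CPM in library 1, 2645 in library 2 and 8577 in library 3. These 3 libraries are the reference of each liver comparison. In female-biased genes, Cyp2a4 was at 300.1 ± 216.7 CPM (SD, n = 3) in liver libraries labelled 11 months and at most 30.8 CPM in the other liver libraries.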
